A study of Homo sapiens with 8 samples.

How the data were processed

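Gene expression was measured in 8 samples of human chordoma cell lines, 3 controls and 1 TNF-α-treated sample for each of U-CH1 and MUG-Chor1. Per the labels' protocols, cells grew as monolayers on gelatin in serum-containing IMDM and RPMI medium, total RNA was extracted with Trizol, and fragmented, biotin-labelled single-stranded cDNA was prepared with a whole-transcript kit. TNF-α was given at 10 ng/mL, in 3 additions a week over 1 week, per the labels and the series' design text. The deposited table holds 1 value per probe set and array, for 53617 probe sets. RMA and Transcriptome Analysis Console are named, without versions, per the submitters' processing notes. No log base is given in the sources used here; the deposited values are taken as log2 from the use of RMA, whose output is log2, and from their range of 0.0648 to 12.7. RMA as usually run equalises the distributions of the arrays, so a change shared by all genes would not be visible. Sorted values of the arrays differed from their mean by a median of 0.0240, so the arrays were already close to a common distribution and were not normalized again. The genome build of the array annotation is not given in the sources used here, so no coordinates are printed. Scanner files and processing dates were not used here, so an array batch that runs with TNF cannot be told apart from it, and no detection call was available to set signal over background.

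Probe sets were named through the supplied platform annotation. Of 53617 probe sets, 23871 had 1 symbol, 1842 had several and 27904 were not listed there. Symbols of 22569 probe sets were matched by Entrez identifier to a RefSeq gene table (assembly GRCh38.p14, used for names and gene types only), which updated 90. Probe sets with 1 symbol covered 22395 genes, and for the 632 genes with several the brightest on average was used. Genes named only through probe sets with several symbols, such as SOD2 and TNFRSF1B, are not analysed here. A gene was tested if it lay above 2.57, the median of all deposited values, on at least 1 array, which left 16986 genes.

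Tests were run with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of adjusted p under 0.05. TNF across both lines came from an additive model of line and TNF over all 8 arrays (5 residual degrees of freedom). TNF in each line, the difference of the TNF effects and the comparison of control lines came from a model of 4 group means (4 residual degrees of freedom), in which the spread comes from the 6 controls and the single TNF array of a line is assumed to vary like them. Fold changes are differences of log2 values, which understate changes of genes near the floor. The design, the gene lists, the naming rule and the alternatives were fixed before the data were examined, except where an alternative or test is said to be added.

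The naming rule took the 14 largest rises and 10 largest falls across both lines with the same sign in each line, the 5 largest each way in each line's contrast and in the difference, and the 10 largest each way between the control lines, among called genes. It also took up to 4 called members of each gene list by size, or the member with the smallest p where none passed, and TNF, TNFRSF1A, TNFRSF1B, NFKBIA, TNFAIP3 and TBXT always. Small RNAs, pseudogenes, uncharacterised loci, sex-linked marker genes and receptor segments were counted but not named. Genes of single arrays quoted for MUG-Chor1 control 3 were chosen after their values were seen.

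A set of 31 gene lists was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry beside it. The fry test asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes.

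The scripts were tested on simulated data over 16986 genes, some of them changed by known amounts. Across both lines, 62.7% of genes changed by a log2 of 1 and 100% of those changed by 2 were recovered, and 8.38% of calls were false. For U-CH1 the recovered shares were 10.4% and 97.0%, for MUG-Chor1 13.4% and 95.5%, for the difference 1.49% and 52.2%, and for the control lines 62.7% and 100%; the false shares of calls there were 4.83%, 7.38%, 9.91% and 6.91%. A shift of 1 in the NF-kB list was found in 20 of 20 simulated sets across both lines, with 0 calls among the 30 unshifted lists. Genes were simulated independently of each other, so this cannot show how often lists of correlated genes would be called falsely. For the test across both lines each changed gene was given the same change in both TNF arrays. All TNF arrays were drawn with the spread of the controls. Recovery and false shares where the lines' effects differ, or where TNF arrays vary more than controls, were not tested.

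Alternatives covered the filter, the choice of probe sets, normalization, the variance model, the threshold, array weights, the model and leaving out each array. Restriction to protein-coding genes and separate fits per line for the agreement were added after seeing the data. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.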

Results

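RNA levels were measured on 8 whole-transcript expression arrays of U-CH1 and MUG-Chor1, 2 human cell lines grown from chordomas. Chordoma is a rare bone tumour of the spine and skull base thought to arise from remnants of the notochord, and TNF-α is an inflammatory cytokine that signals through NF-kB. Each line had 3 control arrays and 1 array from cells given 10 ng/mL recombinant TNF-α in 3 additions a week for 1 week. The arrays were alike in brightness, with medians of 2.52 to 2.63 (log2). Across the genes tested a control array correlated with the other controls of its line at a mean r of 0.960 to 0.970, the U-CH1 TNF array with the U-CH1 controls at 0.943 and the MUG-Chor1 TNF array with the MUG-Chor1 controls at 0.932. The lowest control value, 0.960, belonged to MUG-Chor1 control 3. MUG-Chor1 controls 1 and 2 correlated with each other at 0.981, the highest of any pair of arrays. Control 3 correlated with them at 0.960 and 0.959, near the 0.962 to 0.967 between U-CH1 controls. MUG-Chor1 control 3 also stood apart from controls 1 and 2 in some of the genes named here. CCL2 read 3.11 on it against 1.21 and 0.99, ICAM1 6.75 against 4.55 and 4.24, and C3 8.52 against 5.10 and 4.99. The number of arrays limits the precision, and the single TNF array of each line has no replicate. Nothing in the labels says that the controls came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

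What TNF did in both lines was asked in a model with cell line and TNF as terms. Of 16986 genes tested, 422 changed, 264 upwards and 158 downwards, all with the same sign in both lines. A difference between the lines enters the residual of this model, so a gene with opposite signs could hardly pass. The shared sign is therefore no separate evidence that the lines agree. Inflammatory mediators led the rise. CCL2, a monocyte chemoattractant, rose 41.4-fold (log2 fold change 5.37 ± 0.51, SE; adjusted p = 0.000686), from 2.29 ± 0.30 (SD, n = 3) to 6.86 in U-CH1 and from 1.77 ± 1.16 (SD, n = 3) to 7.94 in MUG-Chor1. CCL5, another chemokine, rose by a log2 fold change of 4.50, FDCSP by 4.32, ANKRD1 by 4.13, the elastase inhibitor PI3 by 3.72, the cytokine IL36B by 3.46 and IL32 by 3.27. INA, which encodes a neuronal intermediate filament, followed at 3.19, the lysosomal protein gene DRAM1 at 3.05 and the transcription factor gene MSC at 2.93. Of 24 tested genes in a list of NF-kB feedback and core targets, 12 rose, none fell and 12 did not pass (16 rose when adjusted over the list alone). TNFAIP3, which restrains NF-kB signalling, rose 9.25-fold (log2 3.21 ± 0.27, SE; adjusted p = 0.000487), the adhesion molecule ICAM1 9.59-fold, VCAM1 8.91-fold and TRAF1 3.78-fold. NFKBIA, the classic NF-kB inhibitor, did not pass across both lines (log2 0.93, adjusted p = 0.294). The NF-kB list ranked above the other genes (camera adjusted p = 3.04e-16), but adjusted p = 0.0600 with an estimated correlation. Of 23 chemokines and cytokines, 8 rose and none fell (10 rose when adjusted over the list alone), IL6 among them at 2.90 (camera adjusted p = 8.11e-09, adjusted p = 0.0600 with an estimated correlation).

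Antigen presentation, immune checkpoint and protease genes held further rises. Among 18 MHC class I presentation genes, 3 rose (9 when adjusted over the list alone): TAPBP by 1.34, the peptide transporter TAP1 by 1.15 and HLA-B by 0.87, whose near-identical relatives leave its identity uncertain (camera adjusted p = 2.16e-07, adjusted p = 0.224 with an estimated correlation). CD74, the invariant chain, rose by 1.48 as 1 of 9 MHC class II genes (1 when adjusted over the list alone; camera adjusted p = 0.194, fry adjusted p = 0.0258). Of 12 immune checkpoint genes, 2 rose (4 when adjusted over the list alone), PDCD1LG2, which encodes PD-L2, by 2.28 and IDO1, which degrades tryptophan, by 1.71 (camera adjusted p = 0.000157, adjusted p = 0.0600 with an estimated correlation). The complement factor gene CFB rose by 2.09 as 1 of 9 complement and acute phase genes (4 when adjusted over the list alone; camera adjusted p = 0.00238, adjusted p = 0.224 with an estimated correlation). Of 19 matrix protease and inhibitor genes, 3 rose (7 when adjusted over the list alone): CTSS by 3.14, MMP9 by 1.97 and MMP1 by 1.35 (camera adjusted p = 0.000157, adjusted p = 0.0600 with an estimated correlation). Of 35 type I interferon-stimulated genes, 0 passed in limma (7 higher and 0 lower at unadjusted p under 0.05; 1 higher when adjusted over the list alone), with IFIH1, a sensor of viral RNA, closest at 2.14 (adjusted p = 0.0521). That list had a camera adjusted p of 0.000155, and adjusted p = 0.554 with an estimated correlation. Its median was 1.34 in U-CH1 and -0.34 in MUG-Chor1, the latter also being its value without the U-CH1 TNF array. Of 19 TNF receptor and death signalling genes, 0 passed in limma (9 higher and 1 lower at unadjusted p under 0.05; 3 higher when adjusted over the list alone; camera adjusted p = 0.0192, adjusted p = 0.371 with an estimated correlation). The TNF transcript itself stood at 0.38 (adjusted p = 0.585) and the receptor gene TNFRSF1A at -0.28 (adjusted p = 0.559).

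Immediate early genes were among those that fell most. FOSB fell 19.4-fold (log2 -4.28 ± 0.35, SE; adjusted p = 0.000487) and FOS 16.0-fold (log2 -4.00 ± 0.43, SE; adjusted p = 0.00113); both encode subunits of the AP-1 transcription factor. Of 17 immediate early transcription factor genes, 3 fell and none rose (9 lower and 1 higher when adjusted over the list alone), KLF2 being the other at -1.73 (camera adjusted p = 2.22e-07, adjusted p = 0.224 with an estimated correlation). The myosin light chain gene MYL1 fell by a log2 fold change of 3.90, MINAR2 by 3.44, the small proteoglycan gene EPYC by 3.07, SCUBE1 by 3.02, PRELP by 2.69, the matricellular gene CCN2 by 2.67, PMP2 by 2.66 and the transcription factor gene ETV1 by 2.63. Of 16 notochord and chordoma markers, 3 fell and none rose (8 fell when adjusted over the list alone): KRT19 by 2.05, SOX5 by 1.69 and TBXT by 1.30. TBXT encodes brachyury, the transcription factor that marks chordoma, and its fall was 2.47-fold (adjusted p = 0.0344). Camera gave this list an adjusted p of 4.16e-08, and adjusted p = 0.224 with an estimated correlation. Of 18 cartilage matrix genes, 4 fell (5 when adjusted over the list alone): ACAN, the aggrecan gene, by 2.43, HAPLN1 by 2.30, FMOD by 2.01 and COL11A1 by 1.31 (camera adjusted p = 0.00358, adjusted p = 0.224 with an estimated correlation).

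Smaller or divided movements were seen in the remaining lists across both lines. Of 17 integrin and adhesion genes, 5 rose, with ITGB3 at 1.49, LAMB3 at 1.28 and L1CAM at 1.12, and ITGA6 fell by 1.48 (6 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.733). Among 21 collagen and matrix assembly genes, LOXL2 rose by 1.17 and COL6A3 fell by 1.83 (2 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.580). CDH11 fell by 1.00 among 18 mesenchymal markers (6 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.526). Among 14 epithelial markers CLDN1 rose by 2.24 and CDH1, which encodes E-cadherin, fell by 1.36 (1 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.180). Of 14 p53 targets, GDF15 rose by 2.40 and GADD45A by 1.36 (3 when adjusted over the list alone; camera adjusted p = 0.00236, adjusted p = 0.347 with an estimated correlation). Of 13 NRF2 and oxidative stress genes, HMOX1 rose by 1.72 and SRXN1 by 1.09 (4 when adjusted over the list alone; camera adjusted p = 0.00222, adjusted p = 0.224 with an estimated correlation). CAVIN2 fell by 1.12 among 5 caveolae genes (2 lower when adjusted over the list alone; camera adjusted p = 0.0607), and HOXA2 by 1.44 among 19 HOX genes (1 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.749).

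Of 24 G2/M and mitosis genes, 0 passed in limma (7 lower and 0 higher at unadjusted p under 0.05; 0 when adjusted over the list alone), with KIF11 at -0.78 (adjusted p = 0.196). The list's median was -0.61 (camera adjusted p = 1.12e-06, adjusted p = 0.424 with an estimated correlation). It was -1.16 in MUG-Chor1 and -0.16 in U-CH1 (camera adjusted p = 0.668), the latter being its value without the MUG-Chor1 TNF array. Of 12 cholesterol synthesis genes, 0 passed in limma (3 higher at unadjusted p under 0.05; 1 higher when adjusted over the list alone), with SC5D at 0.88 (adjusted p = 0.0907; camera adjusted p = 0.0297, adjusted p = 0.424 with an estimated correlation). Another 6 lists held 0 passing genes in limma and no camera call. They covered stemness (10 genes, 2 lower at unadjusted p under 0.05), G1/S and DNA replication (22 genes, 1 higher and 1 lower), the unfolded protein response (13 genes, 1 higher), heat shock (5 genes, none), hypoxia and glycolysis (16 genes, 2 higher) and housekeeping (8 genes, 1 lower). Adjusted over the list alone, 1 stemness gene was lower and none of the other 5 lists had a call. Median, mean and camera direction differed in sign for the collagen, stemness, G1/S, heat shock and housekeeping lists. Among markers of other cell types, DPP4 rose by 1.39 as 1 of 9 fibroblast markers (1 when adjusted over the list alone; camera adjusted p = 0.181). CD68 rose by 0.84 and ITGAM by 0.83 as 2 of 9 leukocyte markers (3 when adjusted over the list alone; camera adjusted p = 0.123, fry adjusted p = 0.0258), and 0 of 7 endothelial markers passed in limma (1 lower at unadjusted p under 0.05; 0 when adjusted over the list alone; camera adjusted p = 0.415). Fry called 5 of the 31 lists in U-CH1, 9 in MUG-Chor1, 0 for the difference of the TNF effects and 10 between control lines. Across both lines camera called 15 of the 31 lists, 11 upwards and 4 downwards, and fry called 10. With an estimated correlation 0 remained across both lines (6 at unadjusted p under 0.05).

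These calls used limma with a two-sided test, adjusted p under 0.05 and 5 residual degrees of freedom, and 2602 genes had an unadjusted p under 0.05. Leaving out U-CH1 control 1 gave 240 genes, MUG-Chor1 control 1 gave 199, MUG-Chor1 control 2 gave 251 and the MUG-Chor1 TNF array gave 216, which is the U-CH1 contrast. Of the 24 genes with the largest changes, EPYC, IL36B, INA and PMP2 lost the call without some control array (adjusted p up to 0.0773), and so did 20 of the 46 called list genes (ACAN, CAVIN2, CD68, CD74, CDH1, CDH11, CLDN1, COL11A1, DPP4, HLA-B, ITGAM, ITGB3, KLF2, L1CAM, LAMB3, LOXL2, SOX5, SRXN1, TAP1 and TBXT; adjusted p up to 0.105).

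Each line's TNF array carried part of these calls. Leaving 1 out leaves 1 TNF array to test, so a gene whose call then ended may still have moved on the remaining array. ICAM1 read 6.04 on the U-CH1 TNF array and 2.85 to 3.35 on the U-CH1 controls, and IL6 7.18 and 4.03 to 5.11. HMOX1 read 7.01 on the MUG-Chor1 TNF array and 5.52 to 6.35 on the MUG-Chor1 controls. The interferon-stimulated list, called upwards across both lines, turned downwards to a median of -0.34 without the U-CH1 TNF array. Without the MUG-Chor1 TNF array 107 of the 422 genes kept the call and 32 calls of named genes ended, those of ICAM1, IL6, TRAF1, DRAM1, PRELP, HAPLN1, KRT19 and TBXT among them, as did the camera calls of the cartilage, G2/M, NRF2 and cholesterol lists. Without the U-CH1 TNF array 211 kept it and 17 ended, those of MINAR2, IDO1, MMP9, HMOX1 and TAPBP among them, as did the camera calls of the complement, death signalling, p53 and cholesterol lists.

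**Figure D1:**
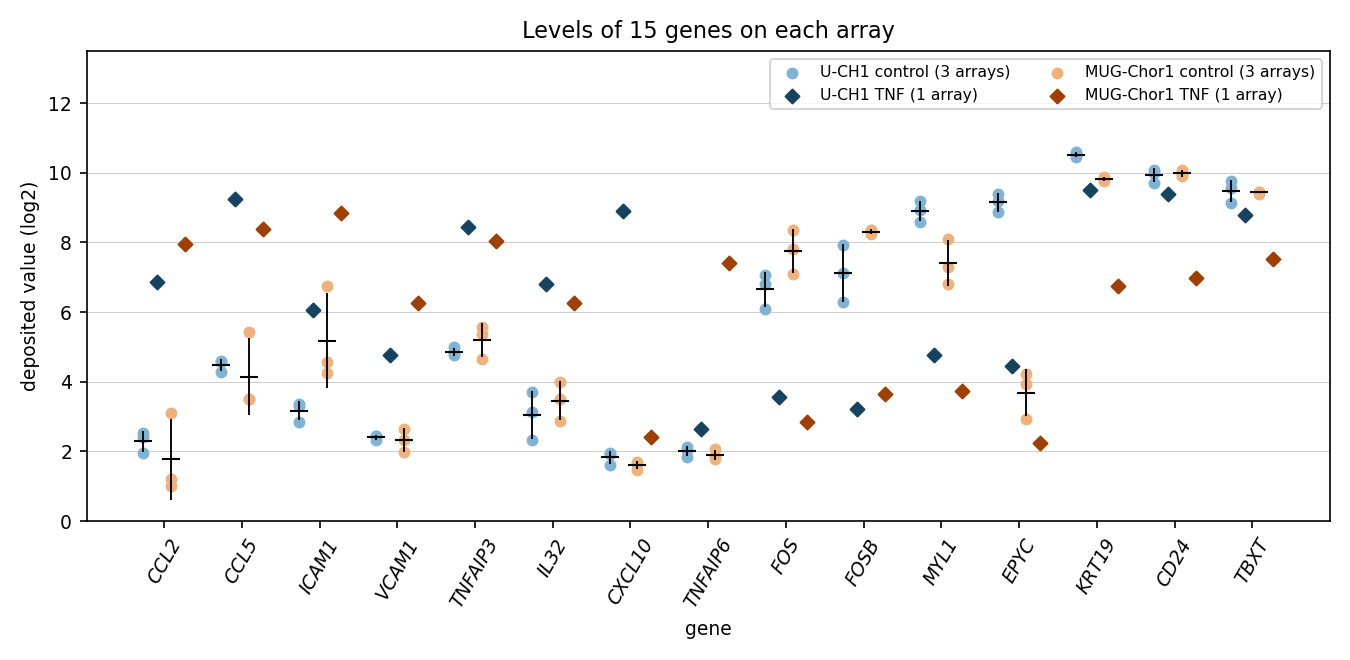
Deposited log2 value (vertical axis) of 15 genes (horizontal axis) on each array; circles are control arrays, diamonds TNF arrays, and black bars the mean and SD of the 3 controls of each line. CXCL10 read 8.91 on the U-CH1 TNF array and 2.41 on the MUG-Chor1 one, while TNFAIP6 read 2.63 and 7.40.

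In U-CH1, TNF changed 216 genes, 155 upwards and 61 downwards, against the spread of the controls. CXCL10, a chemokine for T cells that interferon induces, rose 136-fold, from 1.82 ± 0.18 (SD, n = 3), below the median of all deposited values, to 8.91 (log2 7.09 ± 0.27, SE; adjusted p = 1.09e-06). FDCSP rose by 5.78, PI3 by 5.28, CCL5 by 4.77 and CCL2 by 4.58. EPYC fell by 4.70, MYL1 by 4.14, FOSB by 3.90, MINAR2 by 3.82 and ANKRD20A1 by 3.74; ANKRD20A1 belongs to a family of near-identical copies and its identity is uncertain. Of 35 type I interferon-stimulated genes, 14 rose and none fell (28 rose when adjusted over the list alone). IFIH1 rose 12.6-fold (log2 3.66, adjusted p = 0.000489), IFI6 10.3-fold, OAS2 6.39-fold and the apoptosis factor gene XAF1 5.44-fold. The list's median was 1.34 (camera adjusted p = 4.60e-29, adjusted p = 0.221 with an estimated correlation). Of 24 NF-kB targets, 9 rose (16 when adjusted over the list alone), NFKBIE by 2.52 and NFKBIA by 2.00 among them (camera adjusted p = 2.82e-20, adjusted p = 0.0815 with an estimated correlation).

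Other U-CH1 groups followed with fewer calls. Of 23 chemokines and cytokines, 7 rose (13 when adjusted over the list alone; camera adjusted p = 1.94e-11, adjusted p = 0.154 with an estimated correlation). TNFSF10, which encodes the death ligand TRAIL, rose by 2.47 as 1 of 19 death signalling genes (4 when adjusted over the list alone; camera adjusted p = 0.00889, adjusted p = 0.351 with an estimated correlation). IDO1 rose by 2.41, PDCD1LG2 by 2.00 and ENTPD1 by 1.68 among 12 immune checkpoint genes. CTSS rose by 3.33 and MMP9 by 2.75 among 19 protease genes (3 when adjusted over the list alone; camera adjusted p = 0.0433, adjusted p = 0.311 with an estimated correlation), HMOX1 by 2.37 and GDF15 by 2.36. Of 16 notochord and chordoma markers, 0 passed in limma (3 lower at unadjusted p under 0.05; 1 lower when adjusted over the list alone), with KRT19 at -1.03 (adjusted p = 0.0901) and TBXT at -0.69 (adjusted p = 0.423; camera adjusted p = 0.00171 for the list, adjusted p = 0.311 with an estimated correlation). Of 9 fibroblast markers, 0 passed in limma, 0 lay under an unadjusted p of 0.05 and 0 passed when adjusted over the list alone. Of 9 leukocyte markers, 0 passed in limma (4 higher at unadjusted p under 0.05; 2 higher when adjusted over the list alone; camera adjusted p = 0.0647, fry adjusted p = 0.0401). Their list score was 0.37 on the TNF array and -0.05 to 0.05 on the U-CH1 controls. Of 17 immediate early genes, 2 fell (FOSB and FOS; 2 when adjusted over the list alone; camera adjusted p = 0.000389, adjusted p = 0.424 with an estimated correlation). The single TNF array was assumed to vary like the controls, and 1832 genes had an unadjusted p under 0.05. The count was 122 without U-CH1 control 1, 104 without U-CH1 control 2, 123 without MUG-Chor1 control 1 and 329 without MUG-Chor1 control 3, and the calls of MINAR2, FOS, NFKBIA, IFI6, XAF1, PDCD1LG2, ENTPD1 and GDF15 ended without some control array (adjusted p up to 0.108).

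In MUG-Chor1, TNF changed 489 genes, 250 upwards and 239 downwards. CCL2 rose 71.9-fold (log2 6.17 ± 0.66, SE; adjusted p = 0.000745). TNFAIP6, a secreted hyaluronan-binding protein gene, rose 45.7-fold, from 1.89 ± 0.14 (SD, n = 3) to 7.40, IL36B 43.2-fold, the proton pump subunit gene ATP6V0D2 41.4-fold and INA 31.1-fold. EXOC1L fell 30.3-fold, FOS 30.2-fold, the cadherin gene CDH10 26.4-fold, EGR1 26.3-fold and FOSB 25.2-fold. Of 16 notochord and chordoma markers, 7 fell and none rose (9 fell when adjusted over the list alone). KRT19 fell 8.45-fold, from 9.82 ± 0.05 (SD, n = 3) to 6.74 (log2 -3.08 ± 0.25, SE; adjusted p = 0.000153), CD24 7.97-fold, SOX5 5.45-fold, SOX9 4.85-fold, and TBXT by 1.92 on the log2 scale (adjusted p = 0.00541). The list had a camera adjusted p of 1.45e-12, and adjusted p = 0.0810 with an estimated correlation. Of 18 cartilage matrix genes, 5 fell and 1 rose (the same counts when adjusted over the list alone): ACAN fell by 4.09, HAPLN1 by 3.47, COL2A1 by 2.82 and COL11A1 by 1.96 (camera adjusted p = 0.000113, adjusted p = 0.0810 with an estimated correlation). Beside these falls, 4 of 9 fibroblast markers rose (5 when adjusted over the list alone): FAP by 3.74, LUM by 3.65, DPP4 by 1.89 and DCN by 1.60 (camera adjusted p = 0.00312, adjusted p = 0.416 with an estimated correlation). LUM read 9.34 ± 0.38 (SD, n = 3) in U-CH1 controls and 6.99 ± 0.87 (SD, n = 3) in MUG-Chor1 controls, while FAP rose from 1.97 ± 0.33 (SD, n = 3), below the median of all deposited values, to 5.71. MUG-Chor1 controls 1, 2 and 3 scored 0.25, 0.23 and -0.48 on the fibroblast list, against 1.14 on the TNF array, so control 3 enlarged the rise. Of 7 endothelial markers, KDR, a receptor for VEGF, fell by 2.37 (1 lower when adjusted over the list alone; camera adjusted p = 0.196, fry adjusted p = 0.0237). Their list score was -0.40 on the TNF array and -0.06 to 0.04 on the MUG-Chor1 controls. Of 9 leukocyte markers, 0 passed in limma (2 higher at unadjusted p under 0.05; 1 higher when adjusted over the list alone; camera adjusted p = 0.536, fry adjusted p = 0.130).

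Further MUG-Chor1 groups concerned inflammation, stress and division. Of 24 NF-kB targets, 7 rose (13 when adjusted over the list alone), with VCAM1 at 3.95 and TNFAIP2 at 2.36 (camera adjusted p = 1.13e-08, adjusted p = 0.0810 with an estimated correlation), and 8 of 23 chemokines and cytokines rose and 1 fell (10 and 1 when adjusted over the list alone; camera adjusted p = 1.5e-06, adjusted p = 0.115 with an estimated correlation). PTX3, an acute phase protein gene, rose by 4.95 and the stromelysin gene MMP3 by 3.56. Of 35 interferon-stimulated genes, 0 passed in limma (0 higher and 6 lower at unadjusted p under 0.05; 0 when adjusted over the list alone), with a median of -0.34 (camera adjusted p = 0.00111, adjusted p = 0.557 with an estimated correlation). Of 13 unfolded protein response genes, CHAC1 rose by 2.41 and TRIB3 by 2.06 (6 when adjusted over the list alone; camera adjusted p = 1.95e-05, adjusted p = 0.112 with an estimated correlation), both known targets of the amino acid and endoplasmic reticulum stress response. The cystine transporter gene SLC7A11 rose by 2.56, SESN2 by 2.50 and ADM by 2.57. Of 24 G2/M genes, KIF20A fell by 2.87 (15 fell when adjusted over the list alone), the list median being -1.16 (camera adjusted p = 1.45e-12, adjusted p = 0.370 with an estimated correlation). The MUG-Chor1 controls stood apart on this list, with scores of -0.10, -0.62 and 0.73 for controls 1, 2 and 3, against -1.19 on the TNF array. On the interferon-stimulated list the same controls scored -0.25, -0.09 and 0.34, against -0.29 on the TNF array, which was thus close to control 1. Of 17 immediate early genes, 4 fell (6 when adjusted over the list alone; camera adjusted p = 1.13e-08, adjusted p = 0.222 with an estimated correlation). HES1 fell by 4.11, and NFKBIA stood at -0.15 (adjusted p = 0.935). In limma 2144 genes had an unadjusted p under 0.05. Without MUG-Chor1 control 1 the count was 284, and the calls of CHAC1, DPP4, DCN and KIF20A ended without some control array (adjusted p up to 0.106).

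Whether the lines differed in their response was asked with the interaction contrast, the MUG-Chor1 effect minus the U-CH1 effect. It passed for 90 genes, 34 with a higher value in MUG-Chor1 and 56 with a lower one. CXCL10 differed most downwards among the genes named by the rule, at -6.27 ± 0.38 (SE; adjusted p = 0.000132), with EXOC1L at -4.90, HHLA2 at -4.60, RNASE2 at -4.47 and XYLT1 at -4.28. In U-CH1 controls EXOC1L read 1.17 ± 0.09, HHLA2 2.19 ± 0.20 and RNASE2 2.43 ± 0.56 (SD, n = 3 each), below the median of all deposited values, so these 3 had little room to fall there. MUG-Chor1 controls read 5.73, 5.68 and 6.70. RNASE2 has a near-identical pseudogene and is uncertain. Higher in MUG-Chor1 were the effects on TNFAIP6, by 4.88 ± 0.38 (SE; adjusted p = 0.000498), ATP6V0D2 by 4.87, the peptide gene NMB by 4.39, FAP by 3.95 and IL36B by 3.94. Of 35 interferon-stimulated genes, 6 had a lower effect in MUG-Chor1 and none a higher one (27 lower when adjusted over the list alone), including IFIT1 at -3.61, OAS2 at -3.27, OAS1 at -3.19 and IFIH1 at -3.04. The list median difference was -1.58 (camera adjusted p = 2.38e-34, adjusted p = 0.226 with an estimated correlation). CD24 at -2.47 and KRT19 at -2.05 passed among 16 notochord markers (6 lower when adjusted over the list alone; camera adjusted p = 4.12e-07, adjusted p = 0.226 with an estimated correlation), while the TBXT difference of -1.24 did not (adjusted p = 0.385). ACAN at -3.31 and HAPLN1 at -2.34 passed among 18 cartilage genes (1 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.0131, adjusted p = 0.293 with an estimated correlation). FAP was the 1 of 9 fibroblast markers to pass (4 higher when adjusted over the list alone; camera adjusted p = 0.00485, adjusted p = 0.543 with an estimated correlation).

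This contrast rested on 1 TNF array per line, and 1251 genes had an unadjusted p under 0.05 in limma. Without U-CH1 controls 1, 2 or 3 it gave 39, 40 and 38 genes, without MUG-Chor1 controls 1, 2 or 3 it gave 42, 48 and 152, and HHLA2, IL36B, RNASE2, CD24, KRT19, IFIT1, OAS1, OAS2, HAPLN1 and ACAN each lost the call without some control array (adjusted p up to 0.128).

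The effects of the lines were also set against each other gene by gene. Over the 16986 genes, which are not independent replicates, the log2 fold changes of the lines correlated at a Pearson r of 0.370 and a Spearman rho of 0.315. Both lines called 37 genes higher, where independent lists would share 2.28, and 22 genes lower, where they would share 0.858, while 2 genes were called in opposite directions. Of 644 genes called in either line, 77.5% had the same sign in the other, and for 87 the difference between the lines was itself called. The contrasts share no control arrays but do share the spread estimate. With each line fitted on its own 4 arrays, an alternative chosen after seeing the data, 27 genes were higher in both, against 1.30 for independent lists, and 19 lower in both, against 0.468. Of the 422 genes called across both lines, 107 were also called in the U-CH1 contrast and 211 in the MUG-Chor1 contrast, genes called in both included, and 163 in neither, and for 9 the effects differed.

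**Figure D2:**
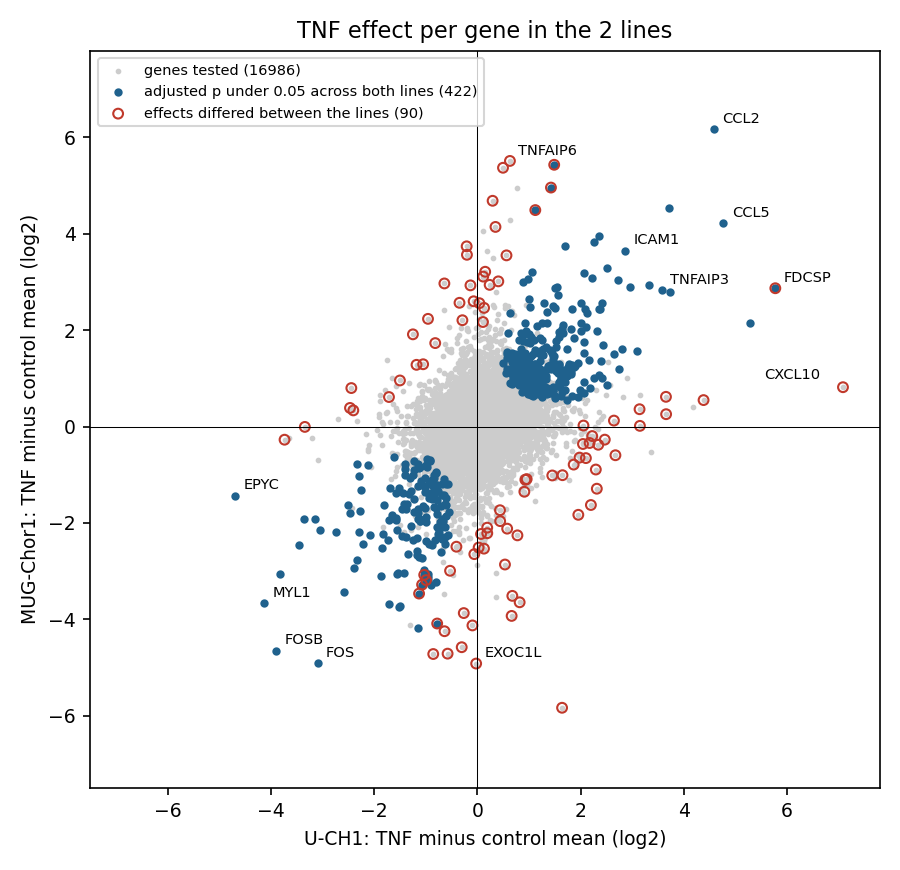
Each point is a gene, with its TNF log2 fold change in U-CH1 on the horizontal axis and in MUG-Chor1 on the vertical axis; grey points are the 16986 genes tested, blue points the 422 called across both lines, and red rings the 90 whose effects differed. CCL2 and CCL5 lie high in both lines, FOS and FOSB low in both, and CXCL10 lies at 7.09 in U-CH1.

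Untreated, the lines differed in 3209 genes, 1754 higher in MUG-Chor1 and 1455 lower, of which 1021 and 795 differed at least 2-fold. Highest in MUG-Chor1 relative to U-CH1 were the histone gene H2BC14 (46.9-fold) and the interferon-inducible gene IFITM2 (45.8-fold), followed by LRRC17, MXRA5, SCRN1, the muscarinic receptor gene CHRM2, FAM83B, EXOC1L, DNAJC15 and the metallothionein gene MT1F at 32.6-fold to 21.0-fold. H2BC14, IFITM2 and MT1F belong to families of similar copies, so their identity is less certain. Lowest were DOC2B (log2 -6.23 ± 0.18, SE; adjusted p = 6.25e-08), the prostaglandin D synthase gene HPGDS at -5.62, EPYC at -5.46, STC1 at -5.32, GDA at -5.22, CAPN6 at -5.12, the desmosome gene DSP at -4.94, NAA38 at -4.93, MAGEC2 at -4.62 and SCIN at -4.57. TBXT did not differ detectably, at 9.48 ± 0.31 in U-CH1 and 9.43 ± 0.03 in MUG-Chor1 (SD, n = 3 each; adjusted p = 0.899). Of 35 interferon-stimulated genes, 18 were higher in MUG-Chor1 and none lower (20 higher when adjusted over the list alone), including IFI6 by 3.16, HERC6 by 2.23, MX1 by 1.95 and RSAD2 by 1.88 (camera adjusted p = 4.25e-08, adjusted p = 0.649 with an estimated correlation). Of 17 immediate early genes, 9 were higher and none lower (9 when adjusted over the list alone), with EGR1 at 3.70, MYC at 2.73 and DUSP1 at 2.26 (camera adjusted p = 2.41e-05, adjusted p = 0.649 with an estimated correlation). As these genes respond within minutes to handling, handling that differed between the lines cannot be told apart from a line difference.

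Other lists also differed between the untreated lines. Of 18 MHC class I genes, 8 were lower in MUG-Chor1 and none higher (2 higher and 8 lower when adjusted over the list alone), with TAP1 at -2.11 and TAP2 at -1.40 (camera adjusted p = 0.00810, adjusted p = 0.651 with an estimated correlation). Of 24 NF-kB targets, 8 were higher (9 when adjusted over the list alone), NFKBIZ 4.73-fold and NFKBIA 2.82-fold among them (camera adjusted p = 0.0140, adjusted p = 0.649 with an estimated correlation). Of 9 complement genes, 4 were higher (4 when adjusted over the list alone), C3 by 3.44 and CD59 by 1.95 (camera adjusted p = 0.0404, adjusted p = 0.649 with an estimated correlation); C3 had an SD of 2.01 in the MUG-Chor1 controls. Of 14 p53 targets, 6 were lower (2 higher and 9 lower when adjusted over the list alone), with ZMAT3 at -1.23 (camera adjusted p = 0.0409, adjusted p = 0.651 with an estimated correlation). Of 16 hypoxia and glycolysis genes, 5 were lower (6 when adjusted over the list alone), with P4HA1 at -2.32 and VEGFA at -1.07 (camera adjusted p = 0.00810, adjusted p = 0.649 with an estimated correlation). TIMP2 was higher in MUG-Chor1 by 3.92 and DPP4 by 3.28, and TNFRSF10D was lower at -3.47. In limma 5389 genes had an unadjusted p under 0.05. Without MUG-Chor1 control 1 the count was 2123, all 20 genes with the largest differences kept their call without each control array, and DUSP1 lost it without 1 of them (adjusted p = 0.0528).

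**Figure D3:**
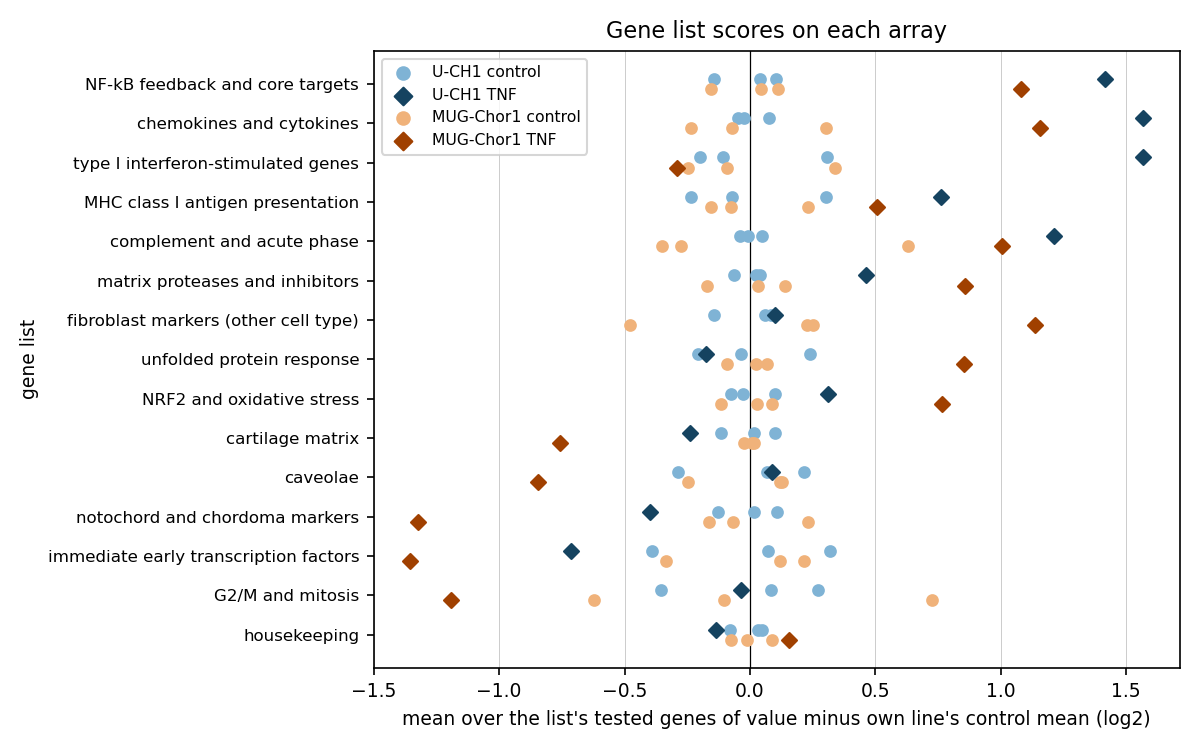
Scores of 15 gene lists (vertical axis) on each array, as the mean over a list's tested genes of the log2 value minus the control mean of the same line (horizontal axis, log2); circles are controls and diamonds TNF arrays. The interferon-stimulated list scored 1.57 on the U-CH1 TNF array and -0.29 on the MUG-Chor1 one, and the notochord list -0.40 and -1.32.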

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

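The tests of keratins KRT8 and KRT18 and of other splits of the arrays were chosen before their results were seen, and all other tests here only after.

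The TNF effect differed between the lines for 90 genes by the test of the difference, given as the MUG-Chor1 effect minus the U-CH1 effect. The effect was higher in MUG-Chor1 for TNFAIP6 (4.88), ATP6V0D2 (4.87), NMB (4.39), FAP (3.95), IL36B (3.94), MMP3 (3.77), INA (3.53), ANKRD20A1 (3.46), LOX (3.06), ADM (2.91), CAPN6 (2.85), TNC (2.70) and SLC7A11 (2.52). It was lower for CXCL10 (-6.27), EXOC1L (-4.90), HHLA2 (-4.60), RNASE2 (-4.47), XYLT1 (-4.28), EGR1 (-4.14), CHRM2 (-4.03), CDH10 (-3.87), IFIT1 (-3.61), ACAN (-3.31), OAS2 (-3.27), OAS1 (-3.19), IFIH1 (-3.04), FDCSP (-2.91), CXCL11 (-2.79), TNFSF10 (-2.74), CD24 (-2.47), HAPLN1 (-2.34), ITGB4 (-2.30) and KRT19 (-2.05). In U-CH1, EXOC1L, CHRM2, HHLA2 and RNASE2 lay at 1.17, 2.14, 2.19 and 2.43 in the control mean, below the filter level of 2.57, so there was little room for a fall there. Of the genes named here, ACAN, ADM, CD24, CXCL11, HAPLN1, HHLA2, IFIT1, IL36B, ITGB4, KRT19, LOX, OAS1, OAS2, RNASE2, SLC7A11, TNC and TNFSF10 lost the call without some control array.

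Camera with its preset correlation called 9 of the 31 lists for this difference, and fry called 0. The median difference of a gene list was -1.58 for interferon-stimulated genes, -1.17 for G2/M genes, -0.98 for caveolae genes, -0.95 for notochord markers, -0.47 for NF-kB targets, -0.34 for immediate early genes and -0.18 for cartilage matrix genes, and 0.84 for the unfolded protein response and 1.01 for fibroblast markers. Each passed with the preset correlation and none with an estimated one, where the adjusted p was 0.226, 0.543, 0.347, 0.226, 0.481, 0.554, 0.293, 0.226 and 0.543 in that order (camera in limma; 4 of the 31 lists at unadjusted p under 0.05).

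Interferon-stimulated genes were higher on the U-CH1 TNF array and not on the MUG-Chor1 one. For 17 members a higher starting level of the gene itself in MUG-Chor1 is argued against. Their median difference was -1.43 (quartiles -2.01 to -1.13, all 17 negative). Their control means lay within 1 log2 unit and were not called between the lines, a rule set after the results were seen. These genes are not independent, and the starting level of the list as a whole is not covered. The list's median was 4.72 in U-CH1 controls and 5.64 in MUG-Chor1 controls, against 5.94 on the U-CH1 TNF array. A single control array is argued against as well, since the list's median difference stayed between -1.89 and -1.49 without each control. An event in the lone U-CH1 TNF culture unrelated to TNF stays open, because its list score of 1.57 (controls -0.20 to 0.31) comes from 1 array. A line difference in the interferon response to TNF is the biological hypothesis. It cannot be told apart from such an event, nor from a higher starting level of the list as a whole.

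Notochord markers were lower on the MUG-Chor1 TNF array, where some fibroblast markers were higher. The fibroblast list scored -0.48 on MUG-Chor1 control 3, which enlarged that rise. Fibroblast-like cells in that culture stay open, with FAP, LUM, DPP4 and DCN higher. The median effect of 8 other fibroblast transcripts (COL1A1, COL1A2, COL5A1, COL6A1, COL6A2, COL6A3, THY1 and PDGFRB) was -0.57 (-2.28 to 0.43, SD 0.80 over the genes). This lay below the value of 1 that the explanation was set to need, and below 0, the bound set against it. The SD of the genes exceeded the distance to that bound. These 8 were chosen after the results were seen and leave out the called markers, so the explanation is not excluded. Of the 9 fibroblast markers tested, 6 lay above the filter level in the control mean of at least 1 line, and 5 are also in other lists. A lower share of chordoma cells stays open too: KRT8 and KRT18 had a mean effect of -0.96, between the bounds set for and against it. Both are members of the notochord list, so their fall cannot tell fewer chordoma cells from a TNF effect on that programme. A TNF effect on the notochord programme is the biological hypothesis, and no replicate of this array was used here.

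Of 17 immediate early genes, 2 were lower on the U-CH1 and 4 on the MUG-Chor1 TNF array, with list calls lost under an estimated correlation (adjusted p = 0.424 and 0.222). These genes respond within minutes to handling, and their median control SD of 0.41 lay at the 99.99th percentile of 10000 random lists matched on level. The random lists were drawn gene by gene and do not reflect members that vary together, so this percentile is not a calibrated test. Handling before harvest stays open: the lowest control score was -0.39, against -0.71 on the U-CH1 and -1.35 on the MUG-Chor1 TNF array. A difference in RNA preparation or labelling stays open too, with a median effect of -0.14 over 160 small nucleolar RNAs (quartiles -0.48 to 0.12), made up of -0.34 over 57 SNORA genes (-0.38 in U-CH1 and -0.33 in MUG-Chor1; 7 lower) and -0.03 over 103 SNORD genes (2 lower), against 0.07 over 14152 protein-coding genes. TNF as the cause is the biological hypothesis, and it cannot be told apart from these.

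Other splits of the arrays were too few for a share under 0.05. Of 16 choices of 1 array per line as the TNF pair, no other gave a gene (highest other 0), against 422 for the real one. Of 10 splits of the 6 controls, no other gave a gene (highest other 0), against 3209 for the real one. Every other TNF pair left at least 1 TNF array among the controls. Each other split of the controls mixed the lines on both sides. Both enlarge the residual, so low counts were built in and lend the real groupings no weight.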

How the results depend on the processing

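Restriction to protein-coding genes was chosen after seeing the data and kept each count within 1.5 times. Testing every probe set gave 191 calls for TNF across both lines, 42 in U-CH1, 295 in MUG-Chor1 and 13 for the difference, against 3469 between control lines; the cause was not tested. Unadjusted p with 2-fold change gave 643, 806, 1100 and 1066, and 1877 between control lines, where adjusted p with 2-fold change gave 1816. The mean of the 2 lines' effects gave 739 across both lines. Its estimates equal those of the additive model, but the model of 4 group means keeps the difference between the lines out of the residual. A fit on the 4 MUG-Chor1 arrays gave 296, and the cause of that was not tested. Leaving out each array gave 199 to 489 across both lines, 104 to 329 in U-CH1, 284 to 664 in MUG-Chor1, 38 to 152 for the difference and 2123 to 3090 between control lines. Of the lists called across both lines, 0 remained with an estimated correlation, and leaving out each array gave 11 to 16. The interferon-stimulated list's median across both lines ran from -0.34 without the U-CH1 TNF array, a reversal, to 1.34 without the MUG-Chor1 one, since each leaves 1 line's effect. The correlation between the lines' effects was 0.355 with no filter, 0.389 with a stricter one, 0.488 over genes called in either line and 0.348 to 0.364 without each control. Deviations of same-numbered controls of the lines correlated at 0.0426, -0.0571 and 0.163 for numbers 1, 2 and 3, and those of other pairs at -0.146 to 0.141. The value for number 3 was the highest, so a factor shared by the controls numbered 3 is not excluded. On the interferon-stimulated list control 3 scored 0.31 in U-CH1 and 0.34 in MUG-Chor1, but on the complement list -0.01 and 0.63. With the replicate block 3248 genes differed between control lines. Of 296 calls of named genes, 183 passed in every setting run for single genes (testing every probe set was not), 113 were lost in some and 0 reversed. Signal over background could not be judged, so changes of genes near the floor are the least certain.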

Other observations

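Adhesion and matrix genes moved both ways in MUG-Chor1 with TNF. Of 17 integrin and adhesion genes, 2 rose and 3 fell (5 and 3 when adjusted over the list alone; camera adjusted p = 0.825): the integrin gene ITGB3 rose by 2.35, while ITGB4 fell by 2.23 and ALCAM by 2.17. Of 21 collagen and matrix assembly genes, 2 rose and 2 fell (3 each way when adjusted over the list alone; camera adjusted p = 0.550), with TNC, the tenascin gene, at 2.94, the crosslinking enzyme gene LOX at 2.93, COL6A3 at -2.28 and COL5A2 at -1.74. The call of COL5A2 ended without MUG-Chor1 control 1 (adjusted p = 0.0701).

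MUG-Chor1 control 3 read apart from controls 1 and 2 in further genes, chosen after their values were seen. CCL5 read 5.43 on it against 3.50 and 3.51, PTX3 4.47 against 2.26 and 3.24, MX1 7.01 against 5.01 and 5.34, and LUM 5.99 against 7.54 and 7.45. Its list scores were 0.63 for complement, 0.73 for G2/M and -0.48 for fibroblast markers, relative to the mean of its line's controls.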
